A study of Homo sapiens with 7 samples.

How the data were processed

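The series holds 7 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from human erythroid cells grown from primary CD34+ progenitors. The labels call the cells erythroblasts, the nucleated precursors of red cells, but the extraction protocol names BFU-Es, an earlier progenitor, and this difference is not settled. Per the labels, the cells entered terminal differentiation medium at day 14 with 1 µM GC-1, a synthetic thyroid hormone receptor agonist, or without it. There was 1 library in each of 7 groups and no replicate. The groups were NCOA4 without GC-1, NCOA4 with GC-1, RNA polymerase, H3K27ac, H3K4me3 and H3K4me1 with GC-1, and input DNA with GC-1. The title of the input names it as the control of NCOA4 with GC-1. NCOA4 is a nuclear receptor coactivator that also carries ferritin to the lysosome.

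The values analysed here come from 1 deposited peak list. Its target is not settled by its sources. The list is attached to the RNA polymerase library, while its name gives NCOA4 with GC-1, its run name begins with a coactivator abbreviation, and the series text says that no peaks were called for the RNA polymerase library. The library title names polymerase I and the series text polymerase II. The text therefore speaks of the deposited peak list, and no value below is assigned to NCOA4 or to a polymerase.

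Per the file headers, the authors called peaks with MACS 1.4.2 against the input, on reads named for hg19. The submitters' processing notes also name cutadapt and Bowtie, whose versions are not given in the sources used here. The header gives an effective genome size of 2.7 Gb, a band width of 300, a p cutoff of 1e-05, a tag size of 39 bp and a model fold range of 5 to 30. MACS estimated a fragment length of 43 bp, kept 1 tag per position, scaled the larger library to the smaller and took the local background from the input over 1000 and 10000 bp. That length is close to the tag size of 39 bp and was not checked against the true size of the fragments. The background per 43 bp and the fold steps given below depend on it. Peak lengths, scores and the number of adjacent peaks may depend on it too, and no call with another length was analysed here. The header counts 8153017 ChIP tags, of which 7552345 stayed after 7.37% were removed as duplicates. It counts 49343248 input tags, of which 17495329 stayed after 64.54% were removed, so the filtered input was 2.32 times as deep as the ChIP.

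The deposited tag counts are whole numbers of ChIP tags per peak after that filter. The deposited score is 10 times the negative log10 of the peak caller's p-value. The deposited fold enrichment is the ratio of the tag pile-up at the summit to the local background. The deposited FDR, in percent, is the number of peaks at or above a score when ChIP and input are swapped, per 100 peaks of the list. All of these are the authors' values and are used only to describe, rank and filter peaks within the list. Coordinates are those of the list, in hg19.

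From these values the number of swapped peaks at each untied rank was recovered as FDR times rank. Peaks less than 10 kb apart were joined into clusters. Peak counts on chromosomes 1 to 22 were tested against chromosome length, taken as the last base of the last peak, by a chi-square statistic with 100000 simulated draws. Peaks per Mb were set against protein-coding genes per Mb, with gene numbers from a RefSeq gene table of assembly GRCh38, and a permutation test with 100000 draws was run. Peaks per 1 Mb window were compared with the highest window in each of 1000 even placements within each chromosome, which ignore gene density and mappability. Intervals for counts are 95% Poisson intervals, those for shares are exact Clopper-Pearson intervals, and those for medians come from order statistics. They cover counting error only. Relations across peaks are Spearman correlations with 1000 bootstrap draws and carry no p-value, because peaks are not independent replicates. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

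The score, FDR and fold bounds, the 10 kb gap, the chi-square test and the relations across peaks were fixed before the data were examined. The bound of 0.2 tags per base that separates tag-dense from other peaks, the clusters of 4 or more peaks, the 1 Mb windows, the share of tags in peaks and the gene density relation were chosen after the data were seen. On simulated lists, a window of 20 planted peaks was found in 20 of 20 runs on 3056 peaks, and no window was called in 20 lists without one. Windows with fewer planted peaks were not simulated. The chi-square test gave a p under 0.05 in 8 of 100 evenly spread lists, and 932 of 932 swapped counts were recovered from rounded FDR values on 3000 peaks.

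The rule for named items was the 15 peaks with the highest score and the 15 with the highest fold enrichment, each with its nearest gene, the members of fixed gene lists that hold a peak, and a fixed set of regulators. No hg19 annotation or sequence was used here, so nearest genes, list members and regulators are not given. Shares of peaks at promoters, in exons and in introns, tests of gene lists and sequence motifs at summits were not analysed here. Peaks on the Y chromosome are not named.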

Results

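The deposited peak list held 3177 peaks, called in 1 ChIP library against input DNA. The labels name the cells as erythroblasts and, in the extraction protocol, as BFU-Es, an earlier erythroid progenitor. With 1 library per group and no replicates, no difference between libraries was tested. The comparison of NCOA4 occupancy with and without GC-1, which the sample groups imply, was not analysed here, and the target of the list is itself not settled. The questions answered below are where the peaks lay, how strong they were and how they compared with the input.

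Among peaks under 0.2 tags per base, the one with the highest score lay in a cluster on chromosome 11, from 5244880 to 5255573. It falls in the region of the beta-globin genes, which encode the beta chains of haemoglobin. Its 4 peaks held 314 tags (95% Poisson interval 280 to 351). That peak, from 5245125 to 5247100, held 197 tags at 29.27-fold enrichment and a score of 1327.87. The adjoining peak, from 5247109 to 5248271, held 95 tags at 31.33-fold enrichment. On chromosome 16, 14 peaks between 219375 and 229912 held 384 tags (347 to 424), with a median fold enrichment of 13.54. That is the region of the alpha-globin genes. In the GRCh38 gene table, the 5 beta-globin genes follow one another without a gap in the order of coding genes on chromosome 11, as do the 5 alpha-globin genes on chromosome 16. A smaller cluster on chromosome 17, from 42325103 to 42345555, had 5 peaks with 61 tags at a median of 17.01-fold. It lies at SLC4A1, which encodes band 3, the anion exchanger of the red cell membrane. Over all peaks, the median fold was 24.94 and the first quartile 19.23. The median of the chromosome 11 cluster, 27.29, was above that median. Those of the chromosome 16 and 17 clusters were below that quartile. The regions named here were picked after their values were seen, and their names come from general knowledge of hg19 and not from an annotation used here.

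Some 1 Mb windows held more peaks than even placement gave. On chromosome 6, the window from 26 to 27 Mb held 33 peaks and the window from 27 to 28 Mb held 23. The window from 149 to 150 Mb on chromosome 1 held 20. By the same general knowledge, these windows include clusters of histone genes, which encode proteins that package DNA, but overlap of peaks with those genes was not tested. The highest window in 95% of the even placements held no more than 11 peaks, and the highest in any of the 1000 placements held 13. Median fold enrichment in these 3 windows was 21.55, 23.09 and 19.5, each below the list median of 24.94. Of 73 core and linker histone genes in the GRCh38 gene table, 55 are on chromosome 6 and 13 on chromosome 1. In all, 11 windows exceeded 11 peaks, and 3 of these, with 12 each, did not exceed the highest placement. Among them, chromosome 10 from 42 to 43 Mb held 23 peaks at 0.482 tags per base and a median of 4.8-fold, chromosome 2 from 133 to 134 Mb held 17 and chromosome 5 from 134 to 135 Mb held 14, all at over 0.2 tags per base. The chromosome 16 window from 0 to 1 Mb, which contains the alpha-globin region, held 17 peaks, as did chromosome 19 from 18 to 19 Mb. When peaks less than 10 kb apart counted once, 3 windows exceeded the 95% limit, which was then 9, and none exceeded the highest placement, 13. They were chromosome 6 from 26 to 27 Mb with 11, chromosome 19 from 18 to 19 Mb with 12 and chromosome 16 from 30 to 31 Mb with 10. The chromosome 6 window from 27 to 28 Mb fell to 6, and the chromosome 1 window and the chromosome 16 window of the alpha-globin region fell to 4 each.

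**Figure D1:**
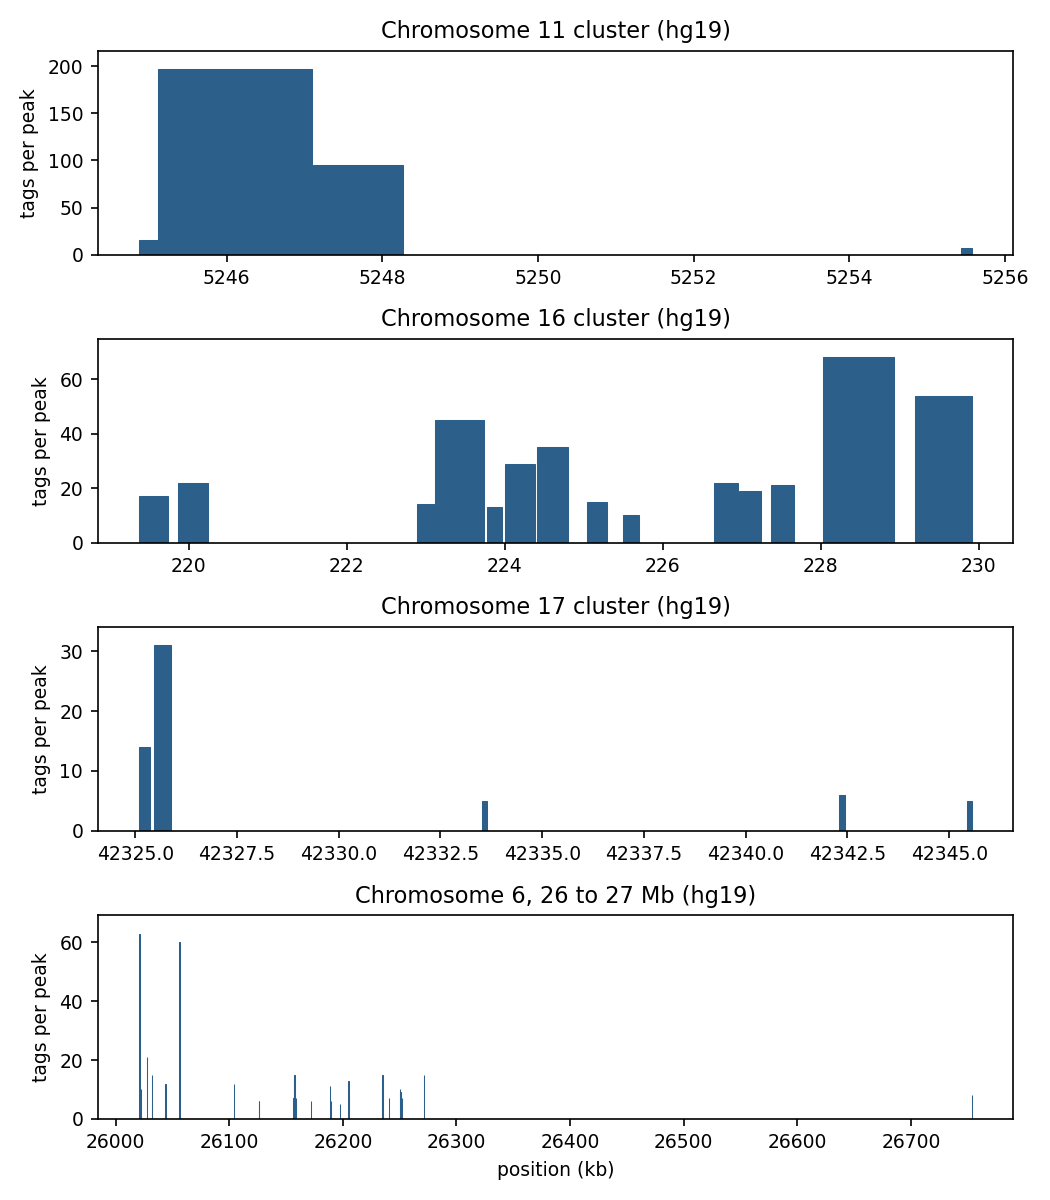
Peaks in the clusters on chromosomes 11, 16 and 17 and in the chromosome 6 window from 26 to 27 Mb, with hg19 position in kb on the horizontal axis and ChIP tags per peak on the vertical axis; each bar spans 1 peak. The chromosome 11 panel shows 197 and 95 tags in 2 adjoining peaks, and the chromosome 6 panel shows 33 separate peaks.

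Across the autosomes, peaks were unevenly spread, with a mean of 1.07 per Mb. Chromosome 19 had the highest density, 3.55 per Mb (95% Poisson interval 3.09 to 4.07). Chromosomes 17 and 16 followed with 2.39 and 1.70 per Mb, and chromosome 13 had the lowest density, 0.47 per Mb. Counts departed from chromosome length (chi-square 691.3, 21 degrees of freedom, p = 1e-05, the smallest that 100000 draws can give). Peak density rose with the density of protein-coding genes over the 22 autosomes. Pearson's r was 0.98 and Spearman's rho 0.93, each with a two-sided permutation p of 1e-05, the smallest the draws can give. Without chromosomes 19 and 17, the 2 farthest from the median gene density, r was 0.91 and rho 0.90. These are relations across chromosomes of 1 library, not across samples, and base composition was not compared.

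**Figure D2:**
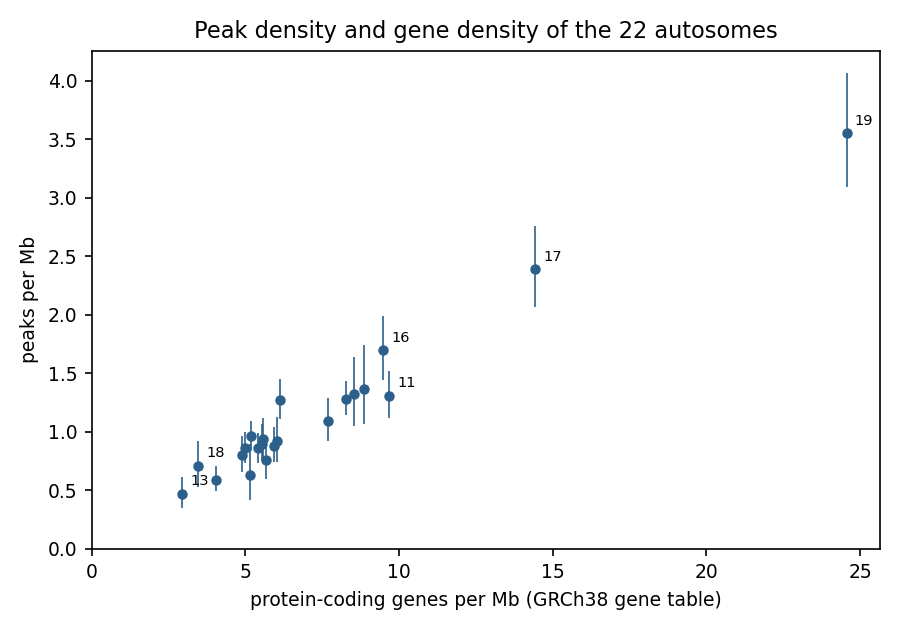
Peaks per Mb (vertical axis, with 95% Poisson intervals) against protein-coding genes per Mb (horizontal axis, gene numbers from GRCh38) for the 22 autosomes; each point is 1 chromosome and the extreme ones are numbered. Chromosome 19, with 3.55 peaks per Mb, lies at the upper right and chromosome 13, with 0.47, at the lower left.

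Most peaks were small. The median peak was 117 bp long (95% interval 116 to 118) and held 6 tags, and 1197 peaks, or 37.68% (35.99 to 39.39), held 5 tags, the lowest number in the list. Median fold enrichment was 24.94 (24.49 to 24.94) and median score 64.7. At this depth the genome-wide background was 0.1203 tags per 43 bp. Where the local background was no higher than that, each stacked tag was worth 8.31-fold. The median fold equalled 3 such steps. In all, 684 peaks (21.53%) had a fold within 0.05 of a whole number of such steps. Peaks contained 0.84% of the filtered tags (0.834 to 0.847), an approximate share because the peak caller shifts tags.

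The 286 tag-dense peaks, with 0.2 or more tags per base, made up 9.0% of the list and held 62.32% of the tags in peaks. They included 14 of the 15 peaks with the highest score. The exception was the chromosome 11 peak in the beta-globin region. The top score, 3100, belonged to a peak on chromosome 21 from 9825436 to 9827631, with 2508 tags at 15.89-fold enrichment. A peak on chromosome 1 from 121484049 to 121485437 was also among these 15, with 1779 tags at 3.09-fold. The 15 peaks with the highest score had a median of 302 tags and a median fold of 19.29. Whether they lie in repeated sequence was not examined.

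The ranking by fold enrichment picked other peaks, and 2 were shared between the 2 lists of 15. The 15 highest folds ran from 249.42 to 342.09, in peaks of 62 to 296 bp with 30 to 81 tags, all of them tag-dense. The highest was on chromosome 20 from 46279824 to 46279950, with 51 tags. Whether these 15 short peaks lie in repeated sequence could not be tested without hg19 sequence. A peak on chromosome 9 from 20414266 to 20414402, with 81 tags at 332.13-fold, was in both rankings. Across all peaks, Spearman's rho between tags and fold was 0.13 (bootstrap interval 0.09 to 0.17), but among tag-dense peaks it was -0.49.

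**Figure D3:**
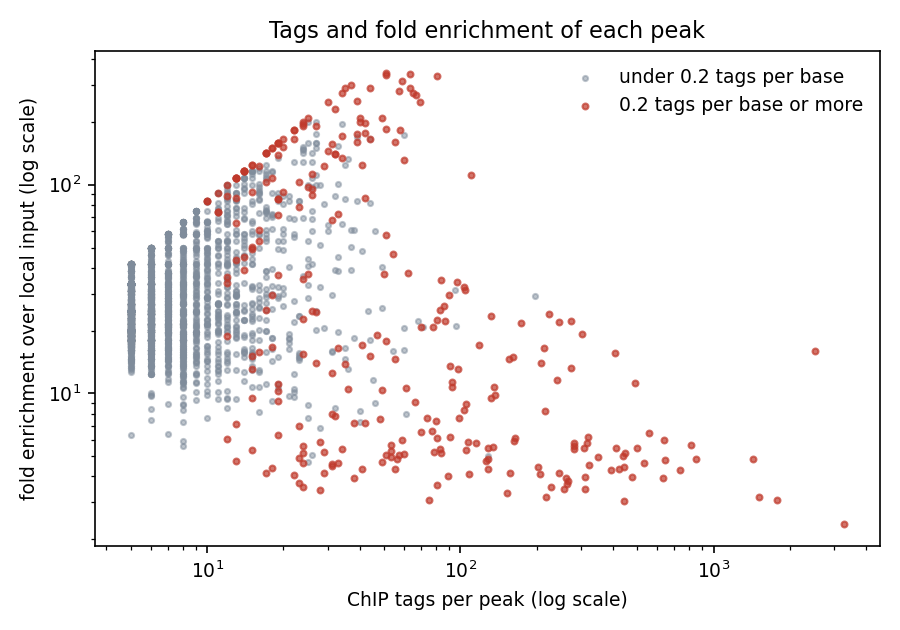
Fold enrichment (vertical, log scale) against ChIP tags (horizontal, log scale) for each peak on the autosomes and X, with peaks of 0.2 or more tags per base in red and others in grey. Tag-dense peaks spread over the whole range of folds, from 2.37 to 342.09, and reach 3278 tags.

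Few peaks stood clear of the input. The 7 peaks with the highest scores had an FDR of 0, and no other peak had an FDR of 5% or less. All 7 were tag-dense, and their folds ran from 3.09 to 22.32, below the list median of 24.94. The beta-globin region peak with 197 tags had an FDR of 16.67%, and FDR in that cluster reached 51.83%. It ran from 40.82 to 57.58% in the alpha-globin region cluster and from 41.63 to 53.9% in the cluster at SLC4A1. At the lowest score in the list, the FDR was 40.89%, which equals 1299 swapped peaks. It was highest, 57.69%, at rank 1197. In all 634 untied scores among the first 1000 ranks, FDR times rank gave a whole number within 0.05. Swapped peaks per 100 list peaks numbered 53.54 (95% Poisson interval 49.22 to 58.14) in the third of the list with the highest scores. They numbered 43.34 (39.47 to 47.5) in the middle part and 25.78 (22.81 to 29.03) in the part with the lowest scores. A score bound of 100 kept 874 peaks, most of which still had an FDR above 40%.

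**Figure D4:**
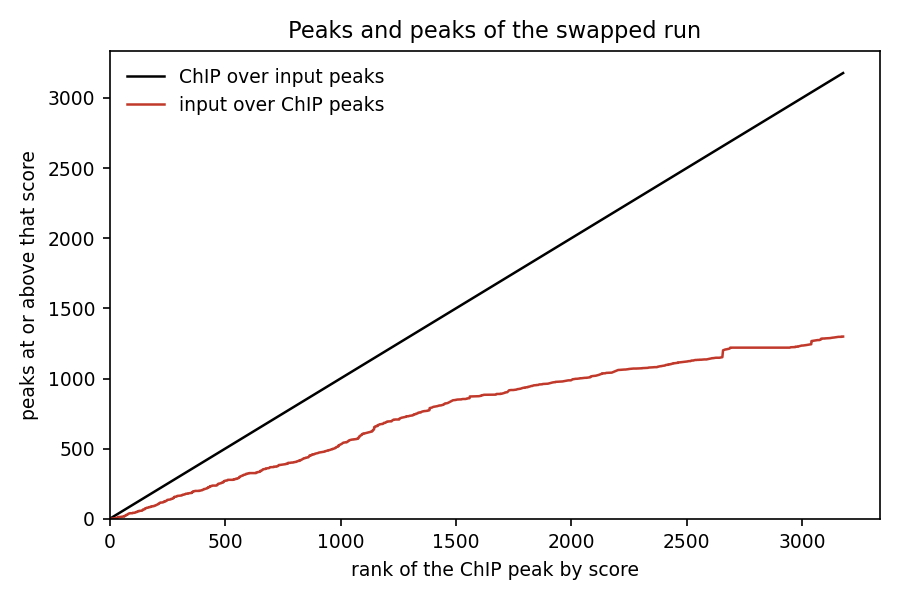
Number of peaks at or above each score (vertical) against the rank of the peak by score (horizontal), for the deposited list (black) and for the run with ChIP and input swapped (red). The swapped run reaches 1299 peaks where the list reaches 3177.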

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

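The tag density bound, the restriction to chromosomes 1 to 22, the first-to-last-peak length, the gene density relation, the windows and the share of tags in peaks were chosen after the data were seen, and the other settings were fixed before. Of 44 alternative values, 23 stayed on the same side of their threshold or within the range set for no change, 19 moved and 2 changed sign. The causes were not tested, except that fewer peaks enter each subset. A score of at least 100 left 874 peaks, with medians of 122 bp, 14 tags and 49.88-fold. An FDR of 5% or less left 7 peaks, with medians of 489 bp, 491 tags and 15.58-fold. In those 7, rho was -0.64 for tags and fold, 0.32 for tags and score and 0.14 for fold and score. Under 0.2 tags per base these were 0.23, 0.73 and 0.64, and at or above it -0.49, 0.05 and 0.68. Without the 1% of peaks with most tags, rho of fold and score was 0.58. Peaks under 0.2 tags per base held 0.317% of filtered tags. Windows over the 95% limit of chance fell from 11 to 3 with 10 kb clusters, and to 3 with 10 kb clusters of peaks under 0.2 tags per base. The chi-square of peaks per autosome and the gene density relation stayed past their thresholds under each alternative run, but chi-square per degree of freedom fell from 32.92 to 21.89 with 10 kb clusters and to 1.82 at 5% FDR, where at most 7 peaks entered. Promoter, exon and intron shares, gene lists, motifs and the length without N bases were planned and not run, since no hg19 annotation or sequence was used. Chromosomes 1 to 22 and X was not run because the donors are people. No paired analysis was possible because each group has 1 library. With 10 tags or fewer in 76.02% of peaks, counting error per peak is wide; no list at another depth was analysed here.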

Other observations

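All tests in this part were chosen after the results were seen. No biological explanation was tested, because the list has no second group to compare.

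Clusters were classed by their tags over all bases covered by their peaks, so a single peak could pass the bound. An example is the peak on chromosome 6 from 26020966 to 26021127, at 0.389 tags per base. In all, 21 clusters of 4 or more peaks fell under 0.2 tags per base and held 124 peaks, the globin, SLC4A1 and histone regions included. Others were 5 peaks on chromosome 19 from 12899411 to 12912519, with 40 tags at a median of 21.55-fold, and 4 on chromosome 8 from 23430975 to 23433282, with 31 tags at a median of 24.81-fold. The 14 tag-dense clusters held 100 peaks. The fullest was on chromosome 10 from 42380036 to 42400752, with 15 peaks and 5312 tags at a median of 4.86-fold. Another, on chromosome 2 from 133011924 to 133019076, ended just over 10 kb before a low-density cluster that began at 133029154. The 10 kb rule alone kept that pair apart.

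For the low-density clusters, extra copies of a sequence would raise the local input. Tags over fold, an upper bound on the local background, had a median of 3.42 times the genome background over the 124 peaks (quartiles 2.31 and 5.92). It was under 5 in 18 of the 21 clusters, and 14.83 on chromosome 16, 15.07 on chromosome 11 and 6.71 on chromosome 2. A lower estimate, tags per base times 43 bp over fold, had a median of 0.96 over the 21 clusters. Because the clusters were picked for low tag density, which lowers both values, extra copies stay open.

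One enriched stretch reported as several adjacent peaks may also crowd a window. After peaks under 0.2 tags per base and less than 10 kb apart counted once, 1 of the 16 windows holding low-density clusters exceeded the 95% limit of 9, which left the question open for them as a set. That was the chromosome 6 window from 26 to 27 Mb, singled out only after that result. It kept 11, below the highest placement of 13, so the question stays open there too. Of the other 15 windows, 0 passed, but most of them had not exceeded the limit of 11 before joining either. Their result therefore cannot show an effect of joining, which makes each cluster 1 peak by construction. Better shearing or recovery of transcribed chromatin could not be tested, since the positions of the swapped peaks are not used here; the FDR reached 51.83% within the chromosome 11 cluster.

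For tag-dense peaks, sequence present in more copies than in hg19 was examined with the lower estimate of the local background. Its median over all tag-dense peaks on the autosomes and X was 8.23 times the genome background (quartiles 0.88 and 25.53). The 14 clusters were examined separately only after that, and their median was 24.81. Picking by tag density raises this estimate, so extra copies stay open for the class and for the clusters. Unlike the globin, SLC4A1 and histone regions, the tag-dense regions were not named from general knowledge. Whether they lie in repeated sequence was not examined, because no hg19 sequence or repeat annotation was used. For width, median length in the class was 125 bp (109 to 146) against 117 bp in other peaks. Median tags were 45.5 against 6. Picking by tags per base favours short peaks with many tags, so this comparison cannot decide on width. Peaks of the 14 clusters were longer, with a median of 263 bp (213 to 375) and 105 tags, and a part for width stays open there too.

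For the high FDR, chance pile-ups just above the p cutoff would put most swapped peaks at low scores. The lowest part of the list had 25.78 swapped peaks per 100, below the middle part. This ratio cannot decide on chance, because chance pile-ups in the ChIP would add list peaks there and lower it. The highest part, with scores of 85.33 or more, already had 53.54 per 100, so the high FDR was not confined to scores near the cutoff. The filtered input was 2.32 times as deep as the ChIP and had lost far more duplicates, and a call at matched depth, which would test this, was not analysed here. Depth therefore stays open.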
